A study of Mus musculus with 6 samples.

How the data were processed

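RNA from hematopoietic stem cells (HSCs) sorted from mouse bone marrow was measured by RNA-seq in 6 libraries, 3 from control mice and 3 from mice exposed to ionizing radiation, all of wild-type genotype. The sort, as the series design gives it, took cells that were lineage-negative, positive for Sca-1, c-Kit and CD150, and negative for Flt3 and CD48. Per the labels' protocols, RNA was purified with a kit for small samples and libraries were made with a strand-specific kit that selects polyadenylated RNA. The radiation dose, the time between exposure and sorting, and the number of mice per library are not given in the sources used here.

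The deposited values are FPKM (fragments per kilobase of transcript and per 1000000 mapped fragments), 1 value per gene symbol and library. Per the submitters' processing notes, reads were handled with fastp, HISAT2 and StringTie on the mouse genome build GRCm38 (mm10); the tool versions, the annotation and the order and settings of these steps are not given in the sources used here. The unit was inferred from the values and the tools named, since the column carries no unit. Each library summed to between 486033 and 490697. The 6 tables held the same 21878 entries in the same order, of which 27 carried a calendar date in place of a gene symbol, as spreadsheet programs write for some symbols; these 27 were left out, leaving 21851 genes. Near-identical genes, such as members of the Ifitm, Wfdc, Ear, H2-Q, globin and histone families, can share reads, so the values of single members are uncertain.

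Depth was estimated from the low values. In genes with a single annotated transcript in GENCODE M21, FPKM multiplied by transcript length gathered at whole multiples of a step in each library: 80 to 98 values lay within 0.01 of a whole multiple at the best step, against a median of 4 to 5 at other steps. These were 25.2% to 29.1% of the low values, too few to recover the reads, so the values were treated as FPKM throughout. The steps correspond to about 14400000 to 16300000 fragments per library. A gene with a transcript of 1 kb at 1 FPKM then rests on about 14.4 to 16.3 fragments, and counting error limits what can be seen near this level.

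Replicates were compared before averaging. Over single-transcript genes, the differences between libraries of a group were 1.25 to 1.67 times those of counting noise (median chi-square over its expected median, 6 pairs). Over the 3 libraries together this was 1.31 to 1.44 in controls and 1.42 to 2.11 in irradiated HSCs, highest for abundant genes. All 6 pairs differed by more than counting noise, which cannot tell separate mice from repeat libraries of 1 sample. The fragment counts behind these ratios were worked back from FPKM, length and step, so the ratios are approximate. Each library was counted as 1 sample because the titles number them as replicates. The labels do not say that the 3 libraries of a group came from separate mice or pools; p-values measure only the spread between these samples, which may be technical.

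Genes with at least 1 FPKM in at least 3 libraries were tested, 10281 in all. Differences were tested on log2(FPKM + 1) with limma 3.58.1 (empirical Bayes with a mean-variance trend, 2-sided) in R 4.3.3, without a replicate block, with Benjamini-Hochberg adjustment and a threshold of 0.05 with no fold minimum. Log2 fold changes, and the counts at a minimum fold, are on the log2(FPKM + 1) scale, which understates the change of genes at low levels; single folds given for a gene without log2 are ratios of the mean FPKM of the groups. The 38 gene lists held 820 symbols, of which 657 were tested; the 36 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The lists covered the sorted markers, HSC identity, ageing and quiescence, p53 targets, DNA repair, senescence, cell cycle and replication histones, interferon, NF-kB and immediate early genes, heat-shock chaperones, endoplasmic reticulum (ER) stress, oxidant defence, respiration, mitochondrially encoded genes, glycolysis, fatty acid oxidation, cholesterol synthesis, autophagy, apoptosis, chromatin regulators, ribosomal proteins, niche receptors, TGF-beta targets, lymphoid, megakaryocyte, erythroid, granulocytic, monocytic, dendritic, B, T and NK, and mast cell, basophil and eosinophil markers, endothelial and stromal markers and sex-linked genes. The groups, test, lists, alternatives and naming rule were fixed before the data were examined.

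The genes named are the 5 sorted markers; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean is at least 5 FPKM, without unnamed or predicted genes and immunoglobulin or T-cell receptor segments; and, of each list, the 4 members with the smallest p, or 6 for p53 targets, HSC ageing, HSC identity and cell cycle. Genes outside this rule are said to be chosen after their values were seen, and a few genes under the rule are not reported here. Gene positions are from GENCODE M21 on GRCm38, counted from 1.

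On simulated data at these depths, with a 2% spread between libraries and 200 changed genes, the test run on 10162 genes for 3 irradiated against 3 control libraries recovered 65.3% of genes changed by 1.2-fold, 98% of those changed by 1.5-fold and 100% of those changed by 2-fold or 3-fold, with 11 calls among 9966 unchanged genes. Alternatives were other pseudocounts, filters, scalings, library weights, thresholds, a replicate block, an estimated correlation in the list test and each library left out in turn. Alternatives with a 1.5-fold minimum and limma's treat test against 1.2-fold were added after seeing the data. Plots used Python 3.11.15 and matplotlib 3.10.9.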

Results

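Gene expression was compared between HSCs of irradiated mice and HSCs of control mice, with 3 libraries in each group. HSCs are the rare bone marrow cells that renew themselves and give rise to all blood lineages, and ionizing radiation damages their DNA. The title of the series speaks of HSCs that age prematurely, and the comparison asks how the transcriptome of these cells differs after irradiation. The steps between low values correspond to about 14800000, 16300000 and 14400000 fragments in control replicates 1 to 3 and 15800000, 14800000 and 14400000 fragments in irradiated replicates 1 to 3. Between 10122 and 10212 genes reached at least 1 FPKM in a library. Values are given as mean FPKM ± SD of 3 libraries, with control before irradiated.

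Irradiated HSCs carried less RNA of lymphoid-priming and interferon-stimulated genes and more RNA of megakaryocytic and erythroid genes and of chaperones. These lists passed the threshold of the camera test at a preset correlation and missed it otherwise (adjusted p = 0.054 to adjusted p = 0.208 with an estimated correlation). Dntt, the terminal transferase of early lymphoid cells, fell from 430 ± 6.62 to 177 ± 2.97 FPKM, and Irf7, a transcription factor of the interferon response, fell from 22.2 ± 0.976 to 8.49 ± 0.175 FPKM. Itga2b, the megakaryocyte integrin CD41, rose from 46.4 ± 0.590 to 72.4 ± 0.668 FPKM, and the ER chaperone gene Hspa5 rose from 315 ± 4.87 to 524 ± 4.41 FPKM. Of 10281 genes tested, 2650 rose, 2972 fell and 4659 were not called (limma, Benjamini-Hochberg adjusted p under 0.05), while 6160 lay under an unadjusted p of 0.05. The called share was thus 54.68%, and the counts of called members in each list below stand against it. Most changes were small: on the log2(FPKM + 1) scale the median size of change among the 5622 called genes was 1.17-fold, and 15 genes rose and 49 fell by at least 2-fold. In 6340 genes (61.7%) the irradiated libraries lay all above or all below the controls. Chance gives 10% if all libraries are independent samples, which the labels do not say. The libraries of a group were very alike, with Pearson correlations across genes of 0.9982 to 0.9985 within groups and 0.9901 to 0.9904 between groups, and the median coefficient of variation of genes at 20 FPKM or more was 2.31% in controls and 2.53% in irradiated HSCs. The first principal component held 80% of the variance and separated the groups.

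**Figure D1:**
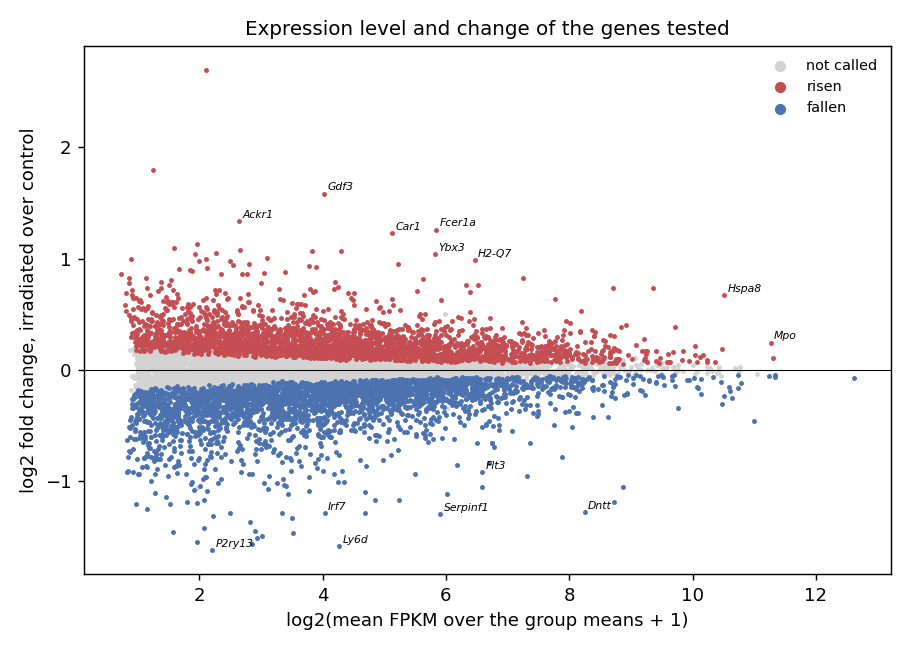
Each point is 1 of the 10281 genes tested, with log2 of the mean FPKM plus 1 on the x axis and the log2 fold change of irradiated over control HSCs on the y axis. Red points are the 2650 genes that rose, blue points the 2972 that fell and grey points those not called.

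The surface markers used for the sort differed in RNA between the groups. Flt3, the receptor whose protein marks multipotent progenitors and was absent by the gate, fell from 125 ± 1.58 to 65.7 ± 1.43 FPKM, a log2 fold change of -0.92 (SE 0.026). Ly6a, which encodes Sca-1, fell from 203 ± 5.13 to 157 ± 5.17 FPKM (log2 fold change -0.37), and Cd48 fell from 400.1 ± 3.36 to 351.6 ± 8.003 FPKM (-0.19). Slamf1, which encodes CD150, rose from 3.57 ± 0.409 to 5.06 ± 0.443 FPKM (0.41). Kit was not called, at 97.5 ± 1.72 and 96.7 ± 1.65 FPKM. Thus 1 of the 5 markers rose and 3 fell, and the markers as a list were not called (camera adjusted p = 0.0923). Cd48 RNA lay above 97.7% of tested genes in each library, whereas Slamf1 lay between the 18.08 and 29.99 percentiles. Mpo, the myeloperoxidase of granulocytic progenitors, stood at 2253 ± 9.23 FPKM in controls, the rank 7 gene by control mean, and rose to 2665 ± 7.99 FPKM in irradiated HSCs.

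**Figure D2:**
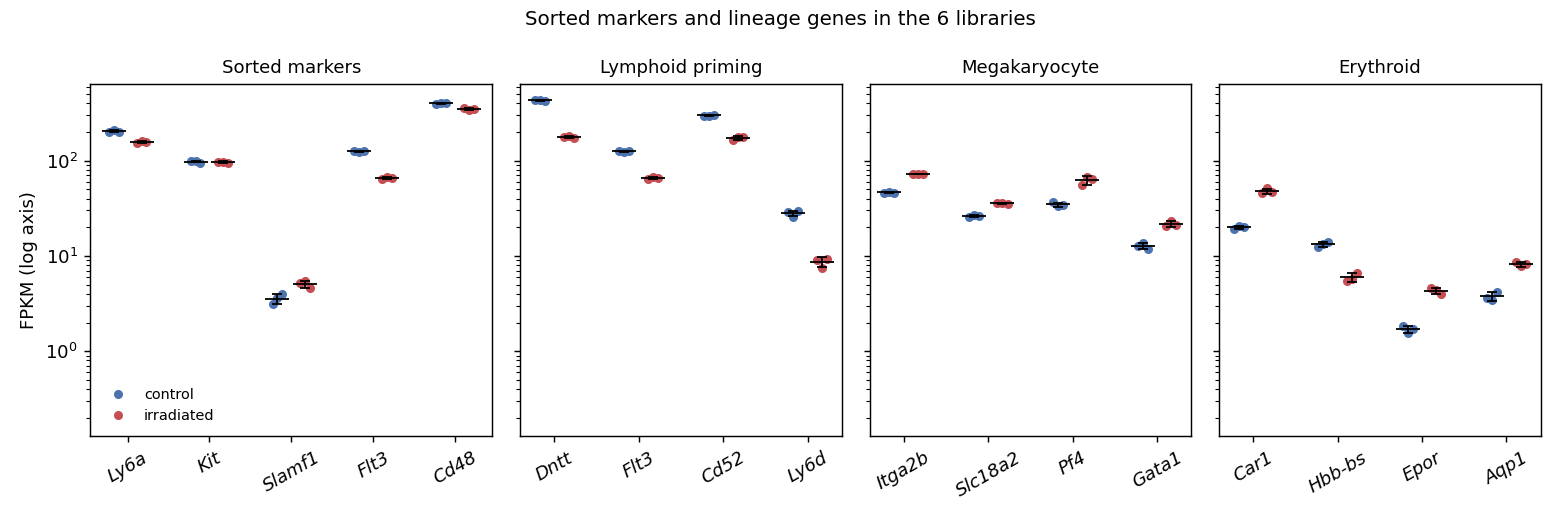
FPKM on a log axis of the sorted markers and of the named lymphoid-priming, megakaryocyte and erythroid genes in each of 3 control (blue) and 3 irradiated (red) libraries, with black marks for the mean and SD. Dntt falls from 430 to 177 FPKM and Flt3 from 125 to 65.7, while Pf4 rises from 34.7 to 62.1 and Car1 from 19.9 to 48.0.

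Among genes with a mean of at least 5 FPKM in the higher group and without predicted genes, the 12 largest rises on the log2(FPKM + 1) scale corresponded to ratios of mean FPKM of 1.998-fold to 3.27-fold. They included genes of basophil and erythroid differentiation. Gdf3, a ligand of the TGF-beta superfamily, rose from 7.14 ± 0.837 to 23.3 ± 1.67 FPKM (log2 fold change 1.58, SE 0.074, limma Benjamini-Hochberg adjusted p = 1.69e-07); it is a protein-coding gene on chromosome 6 from 122605403 to 122610087 (GRCm38). Fcer1a, the alpha chain of the high-affinity IgE receptor (chromosome 1, 173221284 to 173227214), rose 2.44-fold from 32.6 ± 0.503 to 79.6 ± 0.3298 FPKM (adjusted p = 1.03e-09 by limma with Benjamini-Hochberg). Car1, a carbonic anhydrase of erythroid cells, rose 2.41-fold, Klf1, the erythroid Kruppel-like factor, 2.20-fold and Ackr1, the chemokine receptor known as Duffy antigen, 3.11-fold. Aldh1a1, a retinaldehyde dehydrogenase, rose 2.19-fold and Ybx3, a cold-shock domain protein, 2.08-fold. H2-Q7, a class I histocompatibility gene with near-identical neighbours, rose 1.998-fold, and Clca3a1, Cenpv, Adgrl2 and Epdr1 completed these 12, with ratios of 2.47-, 2.23-, 2.57- and 2.32-fold.

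Under the same limits the largest falls included genes of myeloid and lymphoid cells. P2ry13, a purinergic receptor (chromosome 3, 59207892 to 59210882), fell from 5.93 ± 0.279 to 1.26 ± 0.264 FPKM (log2 fold change -1.62, limma Benjamini-Hochberg adjusted p = 2.74e-07). Ly6d, a marker of early lymphoid progenitors, fell from 27.9 ± 1.85 to 8.66 ± 1.06 FPKM, and Blnk, the B-cell linker protein, from 5.66 ± 0.1698 to 1.67 ± 0.127 FPKM. Cd33, a sialic acid-binding receptor of myeloid cells, was 3.49-fold lower, and Ngp, a neutrophil granule protein, 3.11-fold lower. Serpinf1, which encodes pigment epithelium-derived factor, fell from 84.6 ± 2.08 to 33.8 ± 1.60 FPKM. Cox6a2 and Itgb5 were 2.80-fold and 3.29-fold lower, and Wfdc18, Ifitm6 and Ear6, which have close paralogs, were 3.36-, 3.05- and 3.999-fold lower. Irf7 was 2.62-fold lower and completed the 12 largest falls.

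Lymphoid-priming genes fell nearly as a block. Of 14 tested members 13 fell, none rose and 1 was not called, with a median log2 fold change of -0.63; adjusted over the list alone, 13 fell as well. Dntt (chromosome 19, 41029275 to 41059525) had a log2 fold change of -1.28, Ly6d of -1.58, Flt3 of -0.92 and Cd52, a small surface glycoprotein of leukocytes, of -0.78. The list was lower by limma's camera (Benjamini-Hochberg adjusted p = 5.25e-08; adjusted p = 0.054 with an estimated correlation). Across all 37 lists with a tested member, the counts adjusted over the list alone were the same as those over all genes tested in 29, and are given where they were not.

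Megakaryocyte and erythroid genes moved the other way. Of 18 megakaryocyte and platelet genes 13 rose, 3 fell and 2 were not called (median 0.34, camera adjusted p = 0.00129; adjusted p = 0.127 with an estimated correlation). Platelet factor 4 (Pf4) rose from 34.7 ± 1.69 to 62.1 ± 6.44 FPKM, Gata1, a transcription factor of both lineages, from 12.7 ± 0.892 to 21.7 ± 1.57 FPKM, and Slc18a2, a monoamine transporter of platelet granules, from 26.3 ± 0.589 to 35.6 ± 0.790 FPKM. Of 16 erythroid genes 12 rose and 4 fell (median 0.45, camera adjusted p = 0.00725; adjusted p = 0.144 with an estimated correlation). Epor, the erythropoietin receptor, rose from 1.70 ± 0.150 to 4.30 ± 0.306 FPKM and Aqp1, a water channel, from 3.76 ± 0.385 to 8.19 ± 0.467 FPKM. The beta-globin gene Hbb-bs, which has a near-identical copy, went against the list and fell from 13.3 ± 0.707 to 5.94 ± 0.627 FPKM. With the low-value filter raised to 5 FPKM the erythroid list was no longer past the threshold (camera adjusted p = 0.077).

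Interferon-stimulated genes were lower in irradiated HSCs. Of 29 tested members 24 fell, 2 rose and 3 were not called (median log2 fold change -0.45, camera Benjamini-Hochberg adjusted p = 5.25e-08; adjusted p = 0.054 with an estimated correlation). Rtp4 fell from 51.1 ± 0.492 to 22.2 ± 0.552 FPKM, Oasl2 from 30.1 ± 0.299 to 16.8 ± 0.908 FPKM and Dhx58, a regulator of RNA sensing, from 20.3 ± 1.09 to 11.3 ± 0.368 FPKM. NF-kB and inflammatory receptor genes fell in 16 of 23 cases and rose in 2 (3 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.00496; adjusted p = 0.219 with an estimated correlation). Nfkbia, the NF-kB inhibitor, fell from 84.0 ± 1.92 to 54.3 ± 1.60 FPKM, Bcl3 had a log2 fold change of -0.58 and Il18 of -0.82, whereas Tnfaip2 rose by 0.72.

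The lists of monocyte markers, adhesion receptors and endothelial and stromal markers were also lower. Of 17 endothelial genes listed 7 were tested, and which cells carried the RNA of these lists was not tested. Of 16 monocyte and macrophage genes 12 fell, 1 rose and 3 were not called (2 rose adjusted over the list alone; median -0.40, camera adjusted p = 0.00206; adjusted p = 0.127 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 22.1 ± 0.356 to 14.7 ± 0.513 FPKM, Ccr2 had a log2 fold change of -0.47, Cd163 of -0.49 and Lyz2 of -0.22. With a filter of 5 FPKM the monocyte list was no longer past the threshold (camera adjusted p = 0.0521). Of 21 adhesion and niche receptor genes 13 fell, 3 rose and 5 were not called (median -0.16, camera adjusted p = 0.00565; adjusted p = 0.141 with an estimated correlation), among them Notch1 at -0.87, Robo4 at -0.78 and Cd82 at -0.49. Endothelial markers fell in 5 of 7 cases (6 adjusted over the list alone) and rose in none (median -0.46, camera adjusted p = 0.00901; adjusted p = 0.161 with an estimated correlation); Egfl7, which HSCs also express, fell from 159 ± 1.73 to 109 ± 1.97 FPKM and Pecam1 from 43.1 ± 0.239 to 35.2 ± 1.63 FPKM. Emcn and Cldn5, an endothelial tight junction protein, had log2 fold changes of -0.74 and -0.93. All 5 tested stromal markers fell, of 20 on the list (median -0.24, camera adjusted p = 0.0271; adjusted p = 0.245 with an estimated correlation), with Sparc at -0.51, Spp1 at -0.48, Pdgfrb at -0.15 and Igfbp4 at -0.10; without a filter on low values the stromal list was not past the threshold (camera adjusted p = 0.0845).

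**Figure D3:**
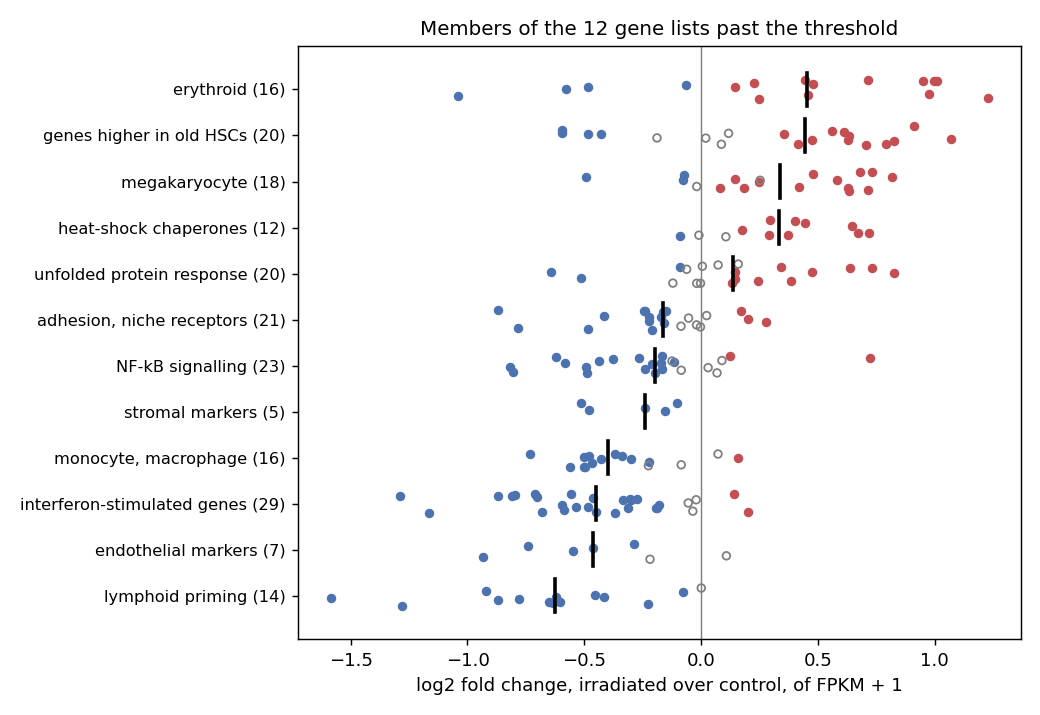
Log2 fold change of irradiated over control HSCs (x axis) for each tested member of the 12 lists past the threshold of the camera test, with the number of members in brackets. Red points rose, blue points fell, open points were not called, and black lines are medians, from -0.63 for lymphoid priming to 0.45 for erythroid genes.

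Heat-shock chaperone genes and ER chaperone genes rose. Of 12 heat-shock chaperone genes, which include the mitochondrial Hspe1 and Hspd1, 9 rose, 1 fell and 2 were not called (median 0.33, camera Benjamini-Hochberg adjusted p = 5.09e-05; adjusted p = 0.121 with an estimated correlation). The constitutive HSP70 gene Hspa8 (chromosome 9, 40800984 to 40810087) rose from 1120.0 ± 18.2 to 1785 ± 27.6 FPKM, Hsp90aa1 from 415 ± 5.62 to 549.5 ± 5.15 FPKM, Hsph1 from 16.3 ± 0.409 to 26.0 ± 0.568 FPKM and Hspe1 from 209 ± 6.87 to 284 ± 6.45 FPKM. In the list of the unfolded protein response 10 of 20 genes rose, 3 fell and 7 were not called (median 0.14, camera adjusted p = 0.00901; adjusted p = 0.208 with an estimated correlation). The members with the smallest p were ER-lumen chaperones: Hspa5 (chromosome 2, 34771970 to 34777547) with a log2 fold change of 0.73, Hsp90b1 of 0.64, Sdf2l1 of 0.83 and Calr of 0.39.

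Genes known to be higher in HSCs of old mice rose as a list. Of 20 tested, 12 rose, 4 fell and 4 were not called (median log2 fold change 0.45, camera Benjamini-Hochberg adjusted p = 0.00904; adjusted p = 0.175 with an estimated correlation). Selp, the adhesion molecule P-selectin (chromosome 1, 164115264 to 164150026), rose from 34.4 ± 0.885 to 56.7 ± 1.33 FPKM. Aldh1a1 rose from 11.8 ± 0.675 to 25.8 ± 1.65 FPKM, Nupr1, a stress-induced chromatin protein, from 12.5 ± 1.72 to 22.4 ± 2.33 FPKM and Clu, the chaperone clusterin, from 2.27 ± 0.154 to 4.06 ± 0.220 FPKM. Itgb3 rose by 0.56 on the log2 scale, and Zg16 by 0.83 from a control level of 0.312 ± 0.155 FPKM, under the filter minimum. Of the 28 genes on the list 20 were tested, and the 4 that fell are named after their values were seen. These were Klrb1c at -0.60, Cd38 at -0.59, Ghr at -0.48 and Alcam at -0.43. The risers Selp and Itgb3 are also known from platelets and megakaryocytes, and Sdpr, which rose by 0.63 and is named after its value was seen, stands on both this list and the megakaryocyte list, in which 13 of 18 genes rose. The median of the ageing list was 0.13 without a filter on low values, 0.20 with a pseudocount of 5 and 0.71 with a filter of 5 FPKM, past the threshold in each case. That filter left only Selp, Nupr1, Aldh1a1, Mt1 and Enpp5, and the median of 0.71 was the value of Selp. Mt1 and Enpp5, named after their values were seen, were not called in the main fit, at log2 fold changes of 0.12 and 0.02.

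Direct p53 targets did not move as a group. Of 23 tested, 8 rose, 5 fell and 10 were not called (9 and 7 adjusted over the list alone; median -0.02, mean -0.02, camera direction up, adjusted p = 0.719). Aen, a nuclease, rose by 0.31 on the log2 scale, Rps27l by 0.24 and the BH3-only gene Pmaip1 by 0.43, while Sesn1 fell from 58.3 ± 1.11 to 39.0 ± 1.22 FPKM and Ephx1 and Dcxr had log2 fold changes of -0.47 and -0.42. Among targets chosen after their values were seen, the cell cycle inhibitor Cdkn1a was at 25.0 and 23.0 FPKM and Mdm2 at 11.4 and 11.9 FPKM, neither of them called, while Bax and Ccng1 rose by 0.24 and 0.16. In the DNA repair list 9 of 28 rose and 5 fell (camera adjusted p = 0.202), with Chek1 at 0.38, Chek2 at 0.30 and Xpc, a nucleotide excision repair gene, at -0.38. Of 9 tested senescence genes 1 rose and 5 fell (camera adjusted p = 0.165): Ccl4 rose by 0.44, and Icam1, Ccl3 and Tnf had log2 fold changes of -0.56, -0.62 and -0.63.

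HSC identity, quiescence and cell cycle lists were not called. In the HSC identity list 7 of 23 genes rose and 10 fell, with a median of 0.0039, a mean of -0.05 and a camera direction of down (adjusted p = 0.51). Ifitm1 fell from 2363 ± 21.2 to 1721 ± 27.6 FPKM and Procr, the endothelial protein C receptor of HSCs, from 19.2 ± 0.494 to 12.6 ± 0.704 FPKM. Ifitm3 and Robo4 had log2 fold changes of -0.34 and -0.78, and Tek, the angiopoietin receptor, rose from 3.09 ± 0.405 to 5.57 ± 0.142 FPKM. Quiescence regulators fell in 8 of 18 cases and rose in 2 (camera adjusted p = 0.0852), with Txnip at -0.49, Ndn at -0.82, Klf2 at -0.96 and Smad4 at -0.34. Among 30 cell cycle genes 13 rose and 7 fell (camera adjusted p = 0.121): the replication helicase genes Mcm2, Mcm3, Mcm5 and Mcm6 rose by 0.25, 0.21, 0.22 and 0.18, and the mitotic genes Cenpa and Cdc20 had log2 fold changes of -0.33 and -0.18. Of 19 replication histones, which share sequence, 8 rose and 1 fell (camera adjusted p = 0.128), among them Hist1h1c at 0.40, Hist1h3c at 0.57, Hist1h4i at 0.50 and Hist1h1a at 0.34.

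Metabolic genes changed in both directions. In glycolysis 12 of 22 genes rose and 4 fell (camera adjusted p = 0.0716): Ldha rose from 974 ± 7.39 to 1131 ± 18.2 FPKM and Pgam1 by 0.24, while Ldhb, the other lactate dehydrogenase subunit, fell from 58.5 ± 0.185 to 30.1 ± 0.880 FPKM and Pdk1 had a log2 fold change of -0.45. Fatty acid oxidation genes fell in 8 of 16 cases and rose in 2 (camera adjusted p = 0.074), with Acadl at -0.28, Acadm at -0.25, Cpt1a, the carnitine shuttle enzyme, at -0.28 and Slc25a20 at -0.25. Of 34 nuclear genes of the respiratory chain 6 rose and 7 fell (camera adjusted p = 0.715), with cytochrome c (Cycs) at 0.23, Cyc1 at 0.19, Sdhc at -0.16 and Uqcrc1 at -0.13. Cholesterol synthesis genes rose in 6 and fell in 5 of 19 cases, with a median of -0.03, a mean of 0.0090 and a camera direction of down (adjusted p = 0.982); Fdps was at 0.29, Lss at 0.52 and Msmo1 at -0.26. In the oxidant defence list 5 of 25 rose and 5 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.786), among them the ferritin genes Ftl1 at -0.25 and Fth1 at -0.17, Gpx4 at -0.13 and Gclm at 0.29. Autophagy and lysosome genes fell in 11 of 24 cases and rose in 2 (camera adjusted p = 0.0741), with Map1lc3b at -0.39, Ctsb at -0.24, Bnip3 at -0.30 and Hexa at 0.26. Mitochondrially encoded genes were not analysed here.

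Among regulators of survival and chromatin, 5 of 21 BCL2 family and caspase genes rose and 6 fell (camera adjusted p = 0.842), with Casp8 at -0.34, Bid at -0.25, Mcl1 at 0.31 and Pmaip1 at 0.43. Chromatin regulators rose in 6 and fell in 15 of 30 cases (16 fell adjusted over the list alone; camera adjusted p = 0.205): the mitochondrial deacetylase Sirt3 fell from 119 ± 1.38 to 86.5 ± 1.59 FPKM, Satb1, a genome organizer of lymphoid cells, from 12.5 ± 0.476 to 7.71 ± 0.0879 FPKM and Ezh1 by 0.35 on the log2 scale, and the histone methyltransferase Setdb1 rose from 7.08 ± 0.315 to 11.5 ± 0.244 FPKM. TGF-beta and BMP targets rose in 3 and fell in 5 of 13 cases (6 fell adjusted over the list alone; camera adjusted p = 0.51), with Id2 at -0.54, Id1 at -0.46, Tgif1 at -0.26 and Skil at 0.30. Immediate early genes rose in 5 and fell in 7 of 16 cases (camera adjusted p = 0.489), with Fos at -0.39, Dusp2 at -0.44, Socs3 at -0.40 and Jun at 0.31. Ribosomal protein genes rose in 14 and fell in 7 of 38 cases (camera adjusted p = 0.113), by small amounts such as 0.17 for Rpl8, 0.22 for Rpl27, 0.14 for Rpl5 and 0.12 for Rps23.

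Markers of other bone marrow cells went in both directions. In the granulocyte list 9 of 18 genes rose and 7 fell, with a median of 0.03, a mean of -0.16 and a camera direction of up (adjusted p = 0.493). With a filter of 5 FPKM this list passed as higher (median 0.24, camera adjusted p = 0.0427). Ms4a3 rose from 219 ± 3.70 to 294 ± 2.79 FPKM and Elane, neutrophil elastase, from 728 ± 16.7 to 949 ± 29.2 FPKM, while Ngp was among the largest falls. Mast cell, basophil and eosinophil genes rose in 6 and fell in 5 of 12 cases, with a median of 0.14, a mean of -0.07 and a camera direction of up (adjusted p = 0.786); the mast cell and basophil genes Fcer1a and Cpa3 rose by 1.26 and 0.29, and the eosinophil granule genes Prg2 and Epx had log2 fold changes of -1.11 and -1.09. Dendritic cell markers rose in 2 and fell in 5 of 10 cases (camera adjusted p = 0.074), with Cox6a2 at -1.33, Ly6d and Flt3 shared with the lymphoid list, and H2-Aa at 0.58. B-lineage and plasma cell genes rose in 2 and fell in 7 of 10 cases (8 fell adjusted over the list alone; camera adjusted p = 0.0569): Jchain, the joining chain of secreted immunoglobulin, rose from 491 ± 6.59 to 817 ± 9.51 FPKM, whereas Blnk, Cd79b and Rag2 had log2 fold changes of -1.32, -0.45 and -0.80. All 7 tested T and NK genes were called, 3 up and 4 down, and the list was not (camera adjusted p = 0.57); Lck and Cd4 had log2 fold changes of -0.87 and -0.92, and Nkg7 and Gzmb rose by 0.28 and 0.81. Of 4 sex-linked genes tested, the Y-linked Eif2s3y fell from 48.6 ± 0.634 to 38.8 ± 1.14 FPKM, and Ddx3y, Kdm5d and Uty were not called, at log2 fold changes of 0.10, -0.11 and 0.10.

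Of the 36 lists tested, 5 were higher, 7 were lower and 24 were not past the threshold. With a pseudocount of 5, which shrinks changes of genes at low levels, the medians of the interferon, NF-kB, unfolded protein response, monocyte, megakaryocyte, erythroid, endothelial and stromal lists were closer to 0 by over 1.5 times and the calls stayed. With an estimated correlation camera placed 0 of the 36 past an adjusted p of 0.05, and 9 lay under an unadjusted p of 0.05.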

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

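Alternatives with a 1.5-fold minimum and with limma's treat test were chosen after seeing the data; the others were planned. None of the 168 genes named by the rule set beforehand reversed or lost its call under another pseudocount, filter, scaling, library weighting or variance trend, the replicate block or a library left out, wherever it was still tested (13 to 17 of these 17 alternatives); a fold minimum ends the call of the smaller changes by construction. Kdm5d without the variance trend (-0.11) and Ddx3y without irradiated replicate 2 (0.15) passed the threshold. The numbers of genes called depended on the fold minimum: 15 rose and 49 fell with a 2-fold minimum, 15 and 50 with an unadjusted p of 0.05 and a 2-fold minimum, 112 and 269 with a 1.5-fold minimum, and 247 and 509 in the treat test against 1.2-fold, since most changes were small. Leaving out each library in turn gave 2320 to 2413 genes higher and 2547 to 2765 lower, with fewer samples in the fit, 5 to 6 lists higher and 7 to 8 lower. Quantile normalization gave 2926 higher and 2674 lower.

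Fitting the replicate number as a block gave 2539 genes higher and 2840 lower, 5 lists higher and 8 lower. Deviations of same-numbered libraries from their group means correlated at 0.0085, -0.0314 and -0.0486, so not every library went best with its own number, and the numbers were not taken to pair the samples. Under the replicate block the B-lineage list passed the threshold (median -0.52).

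Lower lists numbered 4 with a filter of 5 FPKM, since the endothelial and stromal lists kept fewer than 5 tested members and were not tested and the monocyte list (median -0.30) missed the threshold. They numbered 12 with quantile normalization, where the sorted markers, fatty acid oxidation, autophagy, dendritic and B-lineage lists were added; the cause was not tested. Under the 5 FPKM filter the erythroid list (0.34) also missed the threshold, as did the stromal list without a filter (-0.066), where the number of members tested changed. With an estimated correlation 0 lists were higher and 0 lower. In a split chosen after seeing the data, 0 of the 12 lists passed at the preset correlation with the 4 degrees of freedom of that test, and 11 passed at the estimated correlation with the degrees of freedom of the preset test, all but the stromal list (estimated correlation 0.234); the degrees of freedom were thus enough to end the calls. The medians do not depend on it: ageing 0.45, interferon -0.45, NF-kB -0.20, heat-shock chaperones 0.33, unfolded protein response 0.14, adhesion -0.16, monocyte -0.40, lymphoid priming -0.63, megakaryocyte 0.34, erythroid 0.45, endothelial -0.46 and stroma -0.24. Some lists passed the threshold only under an alternative, 15 times over 8 lists, with B-lineage genes doing so most often. With a pseudocount of 5 the medians were 0.20 for ageing, -0.29 for interferon, -0.13 for NF-kB, 0.066 for the unfolded protein response, -0.21 for monocyte, 0.18 for megakaryocyte, 0.26 for erythroid, -0.26 for endothelial and -0.12 for stromal genes, all still past the threshold. Without a filter they were 0.13 for ageing, 0.23 for erythroid and -0.22 for endothelial genes. With a filter of 5 FPKM they were 0.71 for the few ageing genes left and 0.18 for megakaryocyte genes. The granulocyte list then passed as higher (0.24). With a pseudocount of 0.1 the stromal median was -0.38. Depth limits genes near 1 FPKM, where counting error is largest.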

Other observations

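Cirbp, Rsrp1, Nnt and Creld2 were chosen after the results were seen. So were the tests of mature lymphocyte markers, of lymphoid-primed cell shares, of inducible heat-shock genes and of granule genes. The test of other splits was set before its outcome was seen. The tests of length and GC content, of Rbm3 and of further ER chaperones were set after the patterns they address were seen. They were set before their own outcomes, and the bounds for length, GC content and Rbm3 were scaled to the lymphoid median and the fall of Cirbp. Cirbp, the cold-inducible RNA-binding protein gene, fell from 128 ± 4.42 to 61.3 ± 0.562 FPKM, and Rsrp1, a splicing-related gene, from 634 ± 2.07 to 306 ± 1.74 FPKM. Nnt, the mitochondrial transhydrogenase, rose from 16.5 ± 0.369 to 27.2 ± 0.208 FPKM, and Creld2, an ER stress gene outside the lists, from 67.3 ± 1.97 to 115 ± 3.56 FPKM.

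Splitting the 6 libraries into 3 and 3 in other ways gave at most 0 genes in limma, with at most 98 genes under an unadjusted p of 0.05, against 5622 called and 6160 under an unadjusted p of 0.05 for the real split. Each other split mixes libraries of both groups, so the difference between the groups adds to the spread within each side and lowers the calls. The low counts thus do not show how many genes would be called without a group difference. Only 10 splits exist, of which 1, the real one, reached 5622, so the share cannot fall under 0.1.

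Lymphoid-priming genes fell while megakaryocyte and erythroid genes rose. A trend of fold change on transcript length and GC content explained 1.26% of its variance, and its removal took the lymphoid median from -0.63 to -0.59, the megakaryocyte median from 0.25 to 0.31 (17 genes with length and GC content) and the erythroid median from 0.45 to 0.49, which argues against such a trend as the cause. A large share of mature B and T cells in the control libraries is argued against by the markers chosen. The highest control mean of Ms4a1, Cd3e, Cd3d and Cd8a was 0.532 FPKM. Whether such cells carry Dntt, which fell from 430 to 177 FPKM, was not tested. A trace is not excluded, since the highest of these markers, Ms4a1, was at 0.0103 FPKM in irradiated HSCs. Of B-cell genes at higher levels, Cd79a rose from 7.07 to 8.67 FPKM, Cd74 was not called (59.6 and 58.0) and Cd79b fell from 64.9 to 47.1. Fewer lymphoid-primed progenitors among the sorted irradiated cells could give the lymphoid median of -0.63, as could less RNA per cell. Bulk libraries cannot tell the 2 apart. The stated gate (CD150-positive, Flt3- and CD48-negative) would remove such progenitors if it held. Flt3 and Cd48 RNA at 125 and 400.1 FPKM in controls leave open whether it did. An effect of irradiation on the HSCs themselves stays open as the biological explanation the design names.

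Heat-shock and ER chaperones rose together while Cirbp fell. A longer time at a warm temperature before lysis may lower cold-induced genes. Rbm3, which responds to cold like Cirbp, had a log2 fold change of -0.21 (95% interval -0.26 to -0.16). This fell short of the -0.5 that the explanation was set to need, a bound scaled to the fall of Cirbp. The value lay above the -0.25 set for ruling the explanation out, so that bound as written was met. The interval, which was not part of that bound, reached below -0.25. Handling is thus not met by its test, and with the interval counted it is not excluded. A heat-shock response through inducible HSF1 targets stays open, with values that go both ways. The 3 tested of 6 such genes had a median of -0.0091, under the bound written for ruling this response out. That bound was not applied, since only 3 of 6 were tested and these were the members of the chaperone list that did not rise. The heat-inducible Hsph1 and Hsp90aa1 rose. Of the 3 under the filter, Hspa1a, which can share reads with Hspa1b, went the other way, from 0.555 ± 0.121 to 0.0695 ± 0.068 FPKM. Hspa1b and Hspb1 were at 0.0474 and 0.225 FPKM in irradiated HSCs. The 6 ER chaperones outside the fixed list (Manf, Hyou1, Dnajc3, Dnajb11, Canx and Pdia3) had a median of 0.49. A rise of the ER chaperone arm of the unfolded protein response would give this. These are genes of the same kind in the same libraries, so they repeat the pattern and cannot tell this arm from other causes. The ER chaperone arm is a hypothesis, and it does not account for the other chaperones or for Cirbp.

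Cd48 and Flt3 RNA stood at 400.1 and 125 FPKM in control cells sorted as negative for both proteins. The granule genes Mpo, Elane, Prtn3 and Ctsg had a median of 1105 FPKM in controls, and the HSC genes Fgd5 and Mecom stood at 0.594 and 3.37 FPKM. The granule median lay above the control median of the HSC identity list, 9.09 FPKM, which is what was written for progenitors outside the stated gate. That comparison cannot decide between such progenitors and transcription without surface protein, since no cells of another gate were analysed here. The usual levels of these gene sets inside the gate are thus not known. The cells are called HSCs after the series design, and these values do not show how many of them were HSCs. Cd48 and Mpo stood high in both groups, at 352 and 2665 FPKM in irradiated HSCs.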
